A study of Homo sapiens with 2 samples.

How the data were processed

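RNA was sequenced from 2 stable derivatives of SH-SY5Y, an established human neuroblastoma cell line. One had been transfected with an empty vector and the other with a vector expressing sORF1, the small peptide encoded by the long non-coding RNA gene HNF4A-AS1, and both were selected with puromycin. Each group had 1 library. Per the labels, the cells were at passages 15 to 18, total RNA was extracted with Trizol and libraries were made with an Illumina TruSeq RNA kit. Paired-end reads of 100 bp came from an Illumina HiSeq X instrument, per the labels' series design text. The submitters' processing notes name the genome build hg38 and the programs Bowtie2 2.0.6 and TopHat2 2.0.9, and the design text says that reads per gene were counted with HTSeq v0.6.0. The annotation used and the step from counts to deposited values are not given in the sources used here.

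Each deposited table held 1 value for each of 26137 Ensembl genes. The deposited header did not name the unit. The values were treated as FPKM, fragments scaled to gene length in kilobases and to library depth, made by the authors. This reading came from the values themselves. Multiplied by the union exon length in GENCODE release 29, the values of low genes fell on regular steps with 1 step size per library, as counts divided by length and depth do. Every listed gene had a value above 0 in both libraries, so a gene at 0 in either library was not listed and genes present in 1 library alone could not be seen.

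The steps gave the depth. The denominators were 23078304 fragments for the empty-vector library and 30149802 for the sORF1 library. Counts were recovered by multiplying each FPKM value by the gene length and the denominator. They summed to 23596431 and 30819703 over the 25896 genes with a length. Among genes with fewer than 1000 recovered counts, 94.3% in the empty-vector library and 94.4% in the sORF1 library lay within 0.0005 counts of a multiple of 0.01, where 10% would by chance. The share within 0.0005 counts of a whole number was 62.9% and 61.1%. Part of the counts were therefore fractional, which the stated version of HTSeq does not give, and how they arose is not known. The 241 genes without a length in the annotation were left out.

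The design was written for counts, and the files held FPKM. The rules were kept and applied to the recovered counts, with no count model. With 1 library per group there was no residual spread, so no test of the conditions was made and no p-value is given. Library sizes were scaled by the trimmed mean of M values (30% of log ratios and 5% of mean intensities trimmed at each end), written in numpy. The ratio of scaled counts, sORF1 over empty vector, was given with an exact 95% conditional binomial (Clopper-Pearson) interval. These intervals cover counting error only, since PCR reads without molecular identifiers are not independent molecules and the variation between cultures is not included. Log2 ratios were computed after adding 0.5 counts to each scaled library. A gene was measured when its mean scaled CPM over both libraries was at least 1. It was called at least 2-fold higher or lower when the ratio passed 2-fold and the interval lay wholly on that side of 1.

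Before the data were examined, 32 gene lists were fixed. A list with at least 5 measured members was described by its median log2 ratio and by the percentile of that median among 10000 random lists of the same size, matched member by member on mean expression in 20 bins. A list was said to stand apart at a percentile of 2.5 or less, or of 97.5 or more. The counting range of a list median came from 200 Poisson resamples. Chromosomes and runs of 50 neighbouring measured genes were described in the same way.

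The rule for named genes was also fixed in advance. It took up to 12 genes in each direction past the 2-fold rule with a mean CPM of at least 5 and a symbol, the genes of the study itself, the 3 most expressed genes of each library and, in each list, up to 4 members past the 2-fold rule or otherwise the 2 most expressed. Other genes are said to have been chosen after their values were seen. Some genes that the rule takes are not reported here. Coordinates were those of GENCODE release 29 on GRCh38, the same assembly as hg38, matched by Ensembl identifier. Symbols came from a reference list of gene names matched in the same way, and from release 29 where that list had none. The kit is not stated to keep strand, so reads of a gene and of an overlapping antisense gene could not be told apart.

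The alternatives tried were other scalings, filters, fold limits and prior counts, removal of a trend over mean expression, correction for GC content and gene length by loess (span 0.3), and subtraction of the median of 50 neighbouring genes. Correction of the gene counts, chromosomes and single genes for GC content, restriction to whole recovered counts and removal of immediate-early genes from the other lists were added after the data had been seen.

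The rules were tested on simulated data for the comparison of sORF1 with empty vector, run on 25896 genes with 200 genes changed. With counting error only, 94.1% of genes raised 2.5-fold and 97% of genes lowered to 0.4 were called, and 100% of genes raised 4-fold. Of unchanged genes, 0.086% were called. With a dispersion of 0.01 added, 91.2% and 81.8% of the genes changed to 2.5 and 0.4 were called, and 0.27% of unchanged genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.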

Results

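The transcriptome of SH-SY5Y cells stably expressing sORF1 was compared with that of SH-SY5Y cells carrying the empty vector. SH-SY5Y is a human neuroblastoma line, and sORF1 is a small peptide encoded by HNF4A-AS1, a non-coding RNA gene on the strand opposite to HNF4A. The question was how gene expression differs when the peptide is overexpressed. Each group had 1 library, so no difference below has a replicate check and every ratio compares 2 libraries, not the conditions. Values were FPKM, and recovered counts summed to 23596431 in the empty-vector library and 30819703 in the sORF1 library. Intervals in parentheses are 95% and cover counting error only.

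The host gene of the peptide separated the libraries. HNF4A-AS1 (ENSG00000229005; GRCh38 chromosome 20, 44372746 to 44395706, minus strand) had 0.095 FPKM in the empty-vector library and 39.2 FPKM in the sORF1 library. These values rest on 2 and 1078 recovered counts, a ratio of 419 (116 to 3462). The gene lies inside HNF4A on the opposite strand, and its 912 exonic bases overlap no exon of another annotated gene. HNF4A itself (chromosome 20, 44355700 to 44434596, plus strand), a transcription factor of liver and gut epithelium, was near the floor in both, with 31 and 29 counts and a ratio of 0.727 (0.423 to 1.25). The values are per gene, so reads from the expression vector and from the chromosomal copy could not be told apart.

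Apart from that locus the libraries were close. Of 16512 measured genes, 57 were at least 2-fold higher and 36 at least 2-fold lower in the sORF1 library, together 0.56%. The middle 95% of ratios ran from 0.689 to 1.45, and Pearson's r of log2 FPKM across genes, which are not independent replicates, was 0.9918. In 20 simulated draws of unchanged genes with counting error alone, at most 8 genes passed as higher and 7 as lower. In a simulation of this comparison on 25896 genes with a dispersion of 0.01 added, 0.27% of unchanged genes passed, against 0.086% with counting error alone. That dispersion was not fitted to these libraries. Below 100 mean counts the SD of log2 ratios was 0.411, against 0.296 from counting error alone. The 0.27% is therefore no upper limit on the unchanged genes among the calls. Most of the differing genes were scarce, since with a mean CPM of at least 5 the numbers were 9 higher and 1 lower of 12464. Of the 16512 measured genes, 12561 were protein-coding and 665 were processed pseudogenes. Among the 57 higher genes 23 were protein-coding and 20 were processed pseudogenes, and among the 36 lower genes 19 and 2. Processed pseudogenes can share reads with their parent genes, so these 20 and 2 calls are uncertain. The most expressed genes of both libraries were the mitochondrial cytochrome oxidase subunits MT-CO2, MT-CO1 and MT-CO3, with ratios of 0.961 (0.955 to 0.967), 0.98 (0.976 to 0.985) and 1.01 (1.01 to 1.02).

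**Figure D1:**
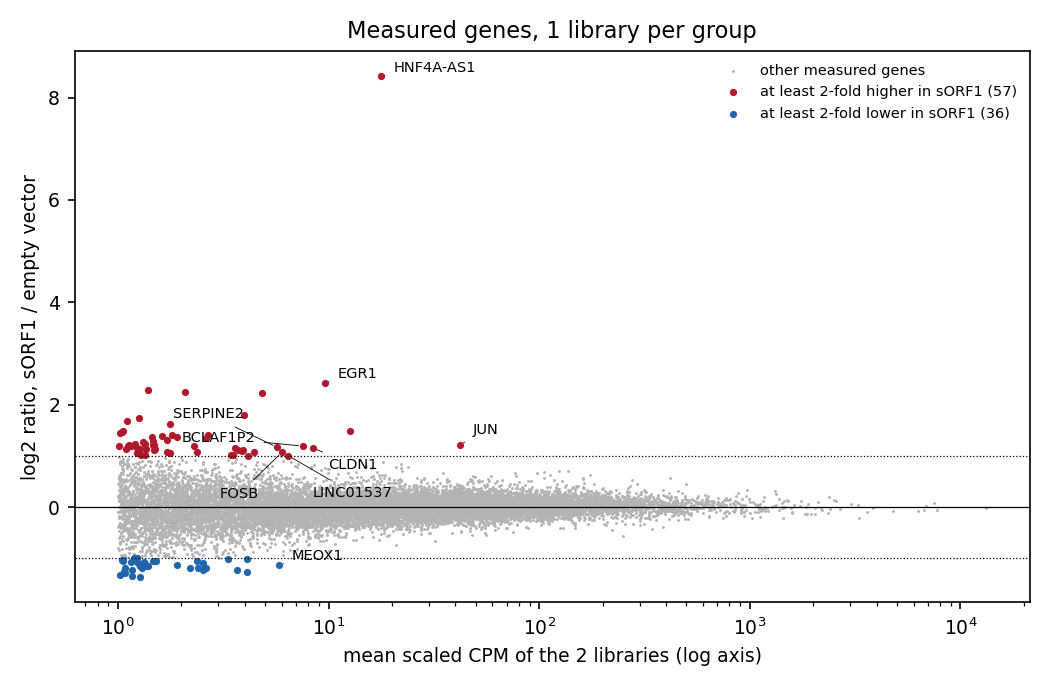
Log2 ratio of sORF1 over empty vector for each measured gene against its mean scaled CPM on a log axis, with 1 library per group. HNF4A-AS1 stands at a log2 ratio of 8.43, EGR1 follows at 2.43 among the named genes, and 57 red and 36 blue points lie beyond the dotted 2-fold lines.

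Among the better expressed genes, the early-response transcription factor genes EGR1, JUN and FOSB were higher in the sORF1 library. EGR1 (ENSG00000120738; chromosome 5, 138465490 to 138469315), a zinc-finger factor induced by growth signals, had 0.98 and 5.23 FPKM, a ratio of 5.42 (4.22 to 7.05). JUN (ENSG00000177606; chromosome 1, 58780788 to 58784327), a subunit of the AP-1 factor, had 7.36 and 16.9 FPKM, a ratio of 2.32 (2.12 to 2.55). FOSB (ENSG00000125740; chromosome 19, 45467995 to 45475179), another AP-1 subunit, had a ratio of 2.10 (1.65 to 2.70). SERPINE2 (ENSG00000135919), a secreted protease inhibitor, had a ratio of 2.26 (1.75 to 2.93) and CLDN1 (ENSG00000163347), a tight-junction protein, one of 2.23 (1.81 to 2.75). The non-coding RNA LINC01537 (ENSG00000227467) had a ratio of 2.01 (1.59 to 2.56). It fell just under the 2-fold limit with total counts (log2 ratio 0.985) and after correction for GC content and length (0.983). The processed pseudogene BCLAF1P2 (ENSG00000279800) had a ratio of 2.29 (1.84 to 2.87), which is uncertain because it can share reads with its parent gene. The named lower gene was MEOX1 (ENSG00000005102; chromosome 17, 43640388 to 43661954), a homeobox factor of mesoderm, with 3.04 and 1.37 FPKM and a ratio of 0.458 (0.359 to 0.581).

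Of the other genes tied to the study, SMAD4, the common mediator of TGF-beta signalling, had a ratio of 1.16 (1.08 to 1.25), and HNRNPU, an RNA-binding nuclear protein, 1.08 (1.07 to 1.09). CTCF, the chromatin insulator protein, stood at 0.973 (0.935 to 1.01). The translation elongation factors EEF1A1 and EEF1A2 had ratios of 0.954 (0.947 to 0.96) and 0.928 (0.91 to 0.945). None of these 5 passed the 2-fold rule. After correction for GC content and length the log2 ratio of EEF1A2 turned from -0.11 to 0.01 and that of HNRNPU went from 0.11 to 0.02. EEF1A1 has many processed pseudogenes that can share its reads, and the exons of CTCF, EEF1A1, HNRNPU and SMAD4 overlap those of another annotated gene. Log2 ratios had an SD of 0.155 among genes with 1000 to 3000 mean counts, as SMAD4 has, where counting error alone gives 0.051. Among genes with 3000 to 10000, as CTCF has, the SD was 0.14 against 0.03, and above 10000, as the other 3 have, 0.115 against 0.016. The intervals are therefore narrower than the spread between the libraries. MYCN was not analysed here.

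Immediate-early genes, which respond within minutes to growth factors and stress, formed the group with the highest median among measured genes. With no filter on low genes the replication-dependent histone list had a higher one. All 27 measured members had a log2 ratio above 0, and their median was 0.43 (counting range 0.35 to 0.49), at the 100th percentile of matched random lists. EGR1, JUN, FOSB and SPRY4, a feedback inhibitor of growth-factor signalling with a ratio of 2.17 (1.32 to 3.71), passed the 2-fold rule, and the other 23 did not. Of the 24 members of the replication-dependent histone list, 12 were listed and 7 were measured. These 7 were also higher, all above 0 with a median of 0.30 (percentile 99.99). That median was 0.20 less the neighbouring genes and 0.46 with no filter on low genes. H1-2 had a ratio of 1.24 (1.14 to 1.34) and H2BC12 one of 1.07 (0.972 to 1.17). Histone genes are near-identical copies and their counts are uncertain.

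Targets of TGF-beta and SMAD signalling had a median of 0.14 (percentile 99.97), with 24 of 34 members above 0 and none past the 2-fold rule. Without the immediate-early members the median was 0.124 (percentile 99.91). Members differed: chosen after their values were seen, KLF10 and CCN1 had ratios of 1.54 (1.46 to 1.63) and 1.49 (1.41 to 1.57). ID1 stood at 1.01 (0.958 to 1.06) and BAMBI at 0.677 (0.557 to 0.823). BHLHE40 stood at 1.13 (1.08 to 1.18) and IGFBP3 at 1.12 (1.08 to 1.17). The components of the TGF-beta and BMP pathways, with TGFBR1 at 1.17 (1.13 to 1.22) and SMAD2 at 1.16 (1.11 to 1.21), did not stand apart at a median of 0.05 (percentile 84.3), but did after correction for GC content and length at 0.11 (percentile 99.8). NF-kB and inflammation genes had a median of 0.14 (percentile 98.6), with 13 of 15 above 0, and IL6, an inflammatory cytokine, was the member past the rule at 2.49 (1.49 to 4.34). Genes of the unfolded protein and integrated stress responses had a median of 0.11 (percentile 99.7), with 17 of 26 above 0. The chaperones HSPA5 and HSP90B1 had ratios of 1.10 (1.08 to 1.12) and 1.04 (1.03 to 1.06). With a mean CPM of at least 5 that list no longer stood apart (0.09, percentile 97.4). Without the immediate-early members it stayed only just apart (0.088, percentile 97.64). MYC targets had a median of 0.10 (percentile 98.2), with 22 of 27 above 0, NPM1 at 1.07 (1.06 to 1.08) and LDHA at 1.03 (1.02 to 1.04). Genes of the mesenchymal neuroblastoma state had a median of 0.13 (percentile 99.8), with 17 of 26 above 0, and the member past the rule, MEOX1, lay in the opposite direction. After subtraction of neighbouring genes that list did not stand apart (0.08, percentile 97.3). Without the immediate-early members its median was 0.101 (percentile 98.52).

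Glycolysis, cholesterol synthesis, extracellular matrix and mitochondrially encoded genes were the lists that stood apart as lower, with no member past the 2-fold rule. Glycolysis had a median of -0.10 (percentile 0.02), with 19 of 25 below 0, GAPDH at 0.934 (0.926 to 0.943) and ENO1 at 0.985 (0.977 to 0.994), and its median was -0.05 after correction for GC content and length. Cholesterol synthesis had a median of -0.08 (percentile 0.08), with 21 of 24 below 0 and HMGCS1 at 1.00 (0.982 to 1.03). Extracellular matrix genes had a median of -0.10 (percentile 0.03), with 14 of 19 below 0, COL4A2 at 0.907 (0.885 to 0.928) and FBN2 at 1.13 (1.10 to 1.16). After correction for GC content and length the matrix median was -0.01 (percentile 22.2) and no longer stood apart. Mitochondrially encoded genes had a median of -0.06 (percentile 1.08), with 11 of 13 below 0 and MT-ND4 at 0.957 (0.951 to 0.962), and did not stand apart once the trend over mean expression was removed (percentile 5.94). After correction for GC content and length their median was -0.11 (percentile 0.02).

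**Figure D2:**
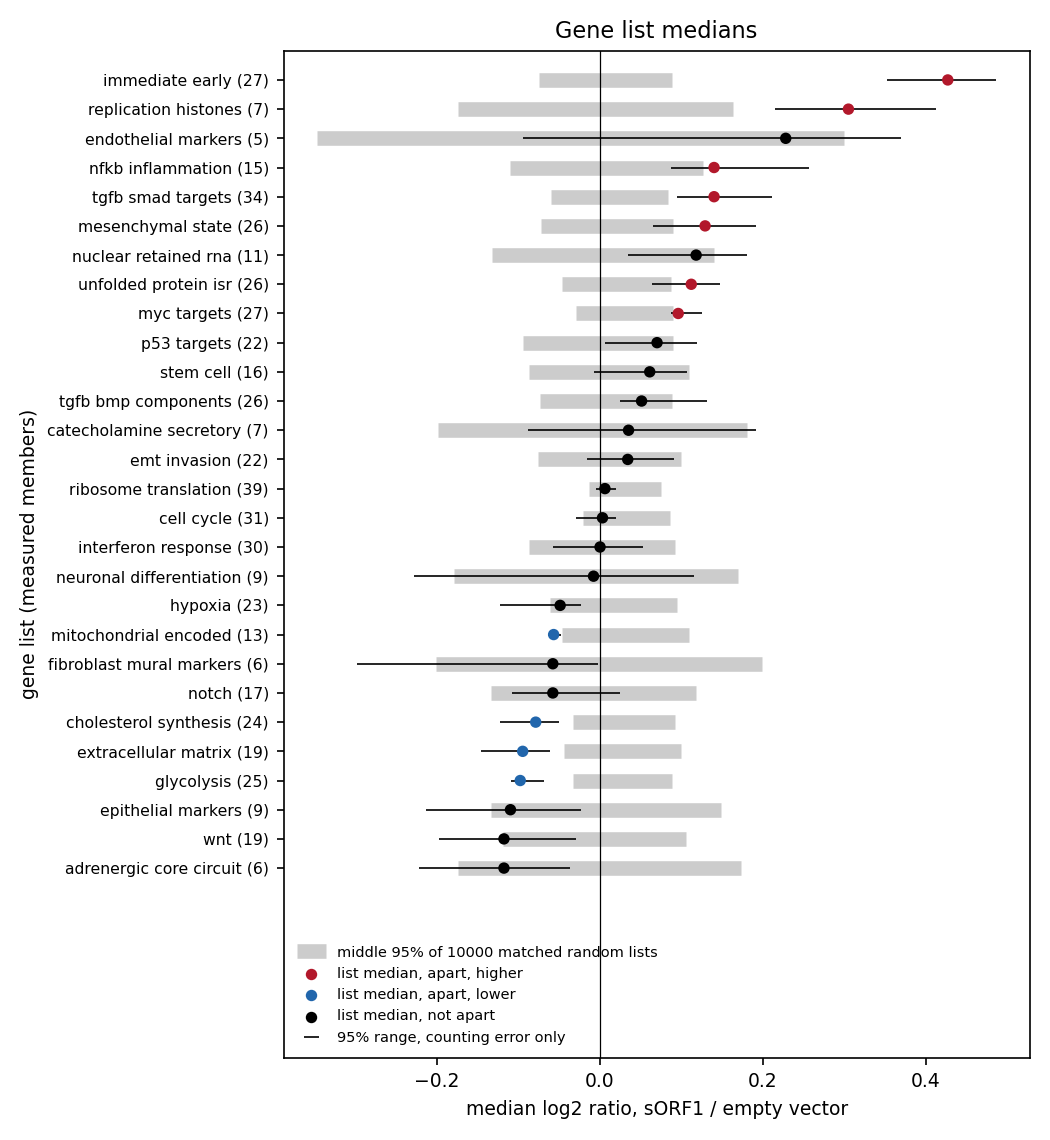
Median log2 ratio of sORF1 over empty vector for the 28 lists with at least 5 measured members, given in parentheses. Grey bars span the middle 95% of 10000 matched random lists and black lines the counting range, and 11 medians, 7 red and 4 blue, stand apart, led by the immediate-early list at 0.43.

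In all, 11 of 28 lists stood apart, where 1.4 would by chance if the ratios of genes varied independently. By the same rule 14 of 23 chromosomes stood apart, and of 319 runs of 50 neighbouring genes 55 as higher and 54 as lower. Random lists were matched on mean expression and not on GC content, which the ratios followed. After correction for GC content and length 3 chromosomes stood apart but 13 lists did, so GC content alone does not account for the number of lists. The 1.4 is a low yardstick for sets of related genes, whose ratios need not vary independently. Cell cycle genes had a median of 0.00 (percentile 14.9), with TOP2A at 1.04 (1.02 to 1.06) and MCM7 at 1.01 (0.99 to 1.04). Ribosome and translation genes, with RPS2 at 0.911 (0.9 to 0.921), had a median of 0.01 (percentile 12.7). The stem cell list, with MYC at 1.08 (1.05 to 1.12) and CD44 at 1.07 (1.03 to 1.12), lay at percentile 84.5. Percentiles were 93.3 for p53 targets, 94.7 for nuclear-retained RNAs, 68.0 for epithelial-mesenchymal transition and invasion, and 47.1 for the interferon response. Hypoxia lay at 4.46, Notch at 19.0 and Wnt at 2.55. Endothelial markers, with CDH5 at 3.27 (1.73 to 6.69) but only 0.281 FPKM in the sORF1 library, lay at 93.9, fibroblast and mural markers at 28.3 and epithelial markers at 4.72. The HNF4A target, Schwann and glial, and immune lists had 3, 3 and 2 measured members and no median was taken. Among them, the HNF4A targets APOM and VIL1 had ratios of 0.853 (0.735 to 0.991) and 1.24 (1.08 to 1.42), the glial genes PMP22 and MBP had 1.21 (1.12 to 1.30) and 1.5 (1.29 to 1.75), and CD68 had 0.861 and 0.977 FPKM.

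Genes of the neuroblastoma lineage were scarce in both libraries. The adrenergic core circuit, catecholamine and secretory, and neuronal differentiation lists hold 81 members, of which 41 were listed. Of these, 23 were under 1 FPKM and 5 at 10 FPKM or more in both libraries. The measured members of the 3 lists had medians of -0.12 (percentile 9.01), 0.04 (percentile 69.0) and -0.01 (percentile 46.2). With a mean CPM of at least 5 the catecholamine and neuronal medians were -0.071 (percentile 27.1) and -0.129 (percentile 5.19), still not apart. Named members were GATA2 with 14.9 FPKM in both libraries, KLF13 with 14.1 and 12.6, CYB561 with 7.38 and 6.92, ENO2 with 14.3 and 11.5 and L1CAM with 34.1 and 29.1. The epithelial keratins KRT8 and KRT18 had 179 and 174 FPKM in the empty-vector library and 154 and 159 FPKM in the sORF1 library.

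Log2 ratios followed the GC content of the genes. The decile of measured genes with the lowest exonic GC content had a median of 0.12 and the decile with the highest one of -0.11, and Spearman's rho across genes was -0.358. Gene length showed no such relation (rho 0.00). Chromosome medians ran from -0.08 on chromosome 22 to 0.07 on chromosome 13, and 14 of 23 chromosomes stood apart from matched gene sets. After correction for GC content and length 3 did, with medians from -0.02 to 0.02. Of 319 runs of 50 neighbouring genes, medians lay between -0.16 and 0.18, and 55 stood apart as higher and 54 as lower, where 16.0 in all would by chance.

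**Figure D3:**
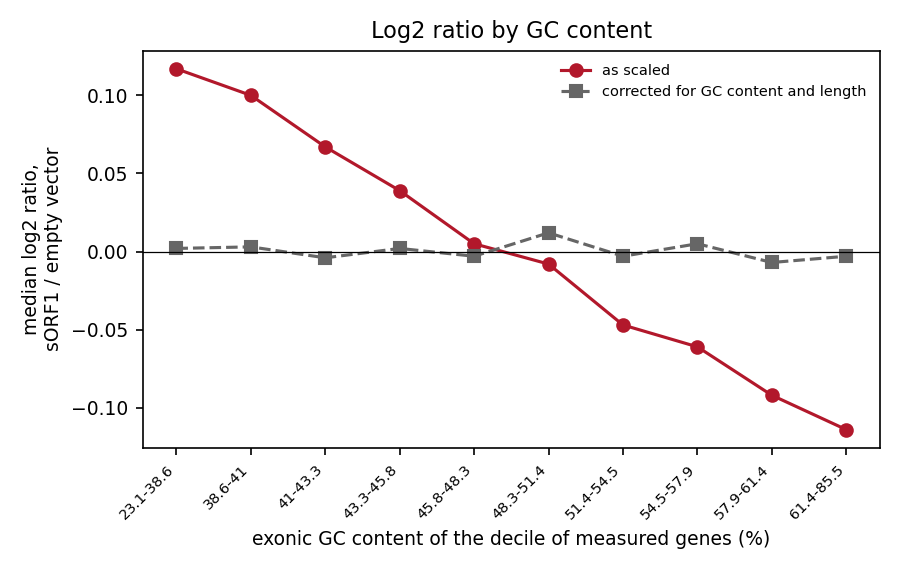
Median log2 ratio of sORF1 over empty vector in 10 deciles of measured genes by exonic GC content in percent, as scaled (red) and after correction for GC content and length (grey). The red medians go from 0.12 to -0.11 while the grey ones stay between -0.01 and 0.01.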

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

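Restriction to whole recovered counts, removal of immediate-early genes from the other lists, and GC correction of gene counts, chromosomes and single genes were tests chosen after the data had been seen. None of the 11 lists that stood apart changed sign under the alternatives run. EEF1A2 (log2 ratio -0.11 to 0.01) and MT-CO3 (0.02 to -0.01) did after correction for GC content and length. Some medians of lists that did not stand apart changed sign too. Notch and fibroblast markers did after that correction, and catecholamine and neuronal lists under another filter. Ribosome genes did with total counts, and ribosome and neuronal lists with the trend over mean expression removed. The cell cycle median of 0.003 fell below 0 with total counts, with that trend removed and after GC correction. It also did less its neighbours (-0.03, percentile 2.76). The count of genes moved with the limits, by their construction. The main counts of 57 higher and 36 lower genes became 261 and 236 without a filter on low genes, 9 and 1 at a mean CPM of at least 5, 254 and 265 at 1.5-fold, 9 and 0 at 3-fold, 32 and 9 with intervals wholly beyond 1.5-fold, 23 and 19 for protein-coding genes and 27 and 18 for whole recovered counts. After correction for GC content and length they were 55 and 43, with 51 and 33 genes shared with the main calls. HNF4A-AS1 kept a log2 ratio of 7.05 with 5 counts added in place of 0.5. Of the 11 lists apart, the same 11 stood apart under both other scalings and with a prior count of 5. They also did with the immediate-early genes removed from the other lists. A list was lost in 4 cases, of which the cause was not tested: mesenchymal state less its neighbours (0.076, percentile 97.3), unfolded protein response at a mean CPM of at least 5 (0.088, percentile 97.4), mitochondrial genes with the trend over expression removed (-0.06, percentile 5.94) and extracellular matrix after GC correction (-0.011, percentile 22.2). Hypoxia, Wnt, p53, epithelial, nuclear-retained RNA and TGF-beta component lists stood apart under some alternatives and not in the main setting. Chromosomes apart went from 14 to 3 after GC correction. Depth limits scarce genes: below 100 mean counts the SD of log2 ratios was 0.411, of which counting error alone gives 0.296. No paired analysis was possible because each group had 1 library.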

Other observations

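The tests on lineage transcripts, on the matrix list by itself and on depth through the trend over expression were written after the result was seen. The corrections used for the matrix list and for depth were among the alternatives planned before. A depth test by thinning was also written before. The genes named in this part were chosen after their values were seen, except JUN, KRT8, KRT18, VIM and CD44.

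Among 8134 genes with a mean CPM of at least 20, 17 were at least 1.5-fold higher in the sORF1 library and 2 at least 1.5-fold lower, with counting intervals excluding 1. Of the 17, 4 belong to the immediate-early list. They are JUN, JUNB at 1.52 (1.42 to 1.64), IER3 at 1.72 (1.52 to 1.95) and ATF3 at 1.59 (1.49 to 1.69). Among the others, KLF10, a TGF-beta-inducible factor, had a ratio of 1.54 (1.46 to 1.63), MAFF 1.63 (1.45 to 1.84), PMAIP1, a pro-apoptotic gene, 1.70 (1.51 to 1.93), TIPARP 1.54 (1.48 to 1.61) and CREM, a cAMP-responsive factor, 1.53 (1.44 to 1.63). KRT17, a keratin, went from 31.0 to 49.6 FPKM, a ratio of 1.62 (1.54 to 1.71).

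As a set, the 665 measured processed pseudogenes had a median log2 ratio of 0.13 (percentile 100 of 2000 matched lists), and 0.09 after correction for GC content and length. Before this median was seen, the upper percentile limit used for the lists had been set for it too. A median above it was what reads shared with parent genes, and split differently between the libraries, would give. The median passed the limit, so the higher pseudogene values may reflect shared reads. The limit cannot single out that cause, since the 441 measured ZNF zinc-finger genes passed it as well. They had a median of 0.10 (percentile 100), and 0.07 after correction.

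Immediate-early genes were higher in the sORF1 library. GC content or gene length bias is argued against as the whole cause, since the list median stayed at 0.424 after correction. A depth effect shared by genes of the same level is argued against too. The medians of measured genes in bins of mean count lay only between -0.043 and 0.036. Removing so small a trend could hardly move the list median, so the 0.404 (percentile 100) left after it adds no evidence. The depth test written before, thinning the sORF1 library to the fragments of the empty-vector library, gave 0.407. Thinning keeps expected ratios, so it could not decide. A depth effect of another kind was not tested. Vector content or handling of the culture remains open: with 1 library per group the peptide, its RNA and any difference in medium, density or harvest cannot be told apart. An effect of sORF1 itself stays untested for the same reason.

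Glycolysis, cholesterol and extracellular matrix lists were lower in the sORF1 library, and ratios also went down with GC content. GC content or gene length bias is not the cause for all of them, because 2 of the 3 lists stayed at or under the 2.5th percentile after correction, glycolysis at 0.67 and cholesterol at 0. The glycolysis median nevertheless moved from -0.098 to -0.052, so part of its shift went with GC content or length, while that of cholesterol moved from -0.079 to -0.104. For the matrix list GC content or gene length bias may account for the shift, since its median moved from -0.10 to -0.01, the 22.1 percentile. An effect of sORF1 stays untested.

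Most adrenergic and neuronal transcripts were not listed or near the floor beside abundant keratins in both libraries. Of 13 lineage genes, 4 were listed (PHOX2A, GATA3, ISL1 and DDC), with none above 1.28 FPKM. KRT7, KRT8 and KRT18 had 68.9, 179 and 174 FPKM in the empty-vector library. Epithelial markers were mixed: of the 11 listed, 4 reached 10 FPKM in both libraries and 4 lay under 1 FPKM in both. The authors' filter on genes at 0 stays open for members that were not listed, and that 23 of the 41 listed members of the 3 neuroblastoma lists lay under 1 FPKM in both libraries restates the pattern. Cells of another type in most of both cultures and a mesenchymal state of the same line stay open and cannot be told apart here: that 5 of the 41 reached 10 FPKM in both restates the pattern, and no reference profile of the line was used. For a mesenchymal state, 9 of 9 collagen, fibronectin and fibroblast markers were under 10 FPKM or not listed (4 not listed). The mesenchymal list median was 3.04 and 2.87 FPKM against 5.24 and 5.19 for all measured genes. These values and the keratins go against it. VIM at 115 and 107 FPKM, YAP1 at 35.9 and 39.8, CD44 at 16.3 and 17.3, AXL at 12.8 and 14.5 and the matrix gene COL5A1 at 29.7 and 25.7 go with it. These genes are among the abundant members of their lists, however. Of the 29 listed members of the mesenchymal list, 6 reached 10 FPKM in both libraries and 7 lay under 1 FPKM in both.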
